A study of Mus musculus with 18 samples.

How the data were processed

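The samples were stomach tissue close to the pylorus, pylorus and duodenum of C57Bl/6J mouse embryos at E14.5 and E16.5. Per the labels' protocols, 174 embryos of E14.5 and 95 of E16.5 were dissected and the tissue of each kind was randomly pooled into 3 samples per group. Whether each of the 18 arrays holds a separate pool is open for the first 2 duodenal arrays of E14.5, as described below. Per the labels' protocols, total RNA was extracted with TRIzol and RNeasy and labelled as biotinylated cRNA for Affymetrix arrays.

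The deposited values are log2 intensities for which the authors list the tools GCOS and RMA, per the submitters' processing notes. The versions of both tools are not given in the sources used here, and neither is whether all arrays went through a single RMA run. The deposited table holds 45101 probe sets with log2 values from 3.55 to 15.22, and array medians lay between 6.75 and 6.92. No further scaling was applied.

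Probe sets were named from the array annotation. Of them, 34945 carried exactly 1 gene symbol, 932 carried several, 9160 were not listed or had no symbol, and 64 were Affymetrix controls. Only probe sets with exactly 1 symbol were used, and the probe set with the highest mean over the 18 arrays stood for its gene, which gave 18193 genes, 9010 of them with more than 1 probe set. The gene identifiers of 34741 named probe sets were found in a RefSeq gene table of assembly GRCm38.p6, used for names alone, and 0 symbols were updated.

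Replicates of each group were compared before the fit. Over probe sets above log2 8, the SD of the difference between duodenal replicates 1 and 2 of E14.5 was 0.079, against 0.177 to 0.497 in the other 17 pairs. The differences of 2 probe sets of the same gene correlated at 0.007 in that pair (95% interval from 1000 resamples -0.034 to 0.05, 2689 genes) and at 0.308 to 0.733 in the others. As 1 pool hybridized again would give such values, these arrays were averaged into 1 sample. The design written before the data were examined counted 18 separate arrays, so the fit departs from it with 17 samples.

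Genes were tested with limma 3.58.1 in R 4.3.3, with a mean for each of the 6 groups, empirical Bayes variances (11 residual and 3.95 prior degrees of freedom) and Benjamini-Hochberg adjusted p under 0.05 as the threshold. The comparisons were duodenum minus stomach, pylorus minus stomach and pylorus minus duodenum at each age, E16.5 minus E14.5 in each tissue, and the change of each tissue difference with age. A gene counted as higher in pylorus than in both neighbours when both differences were called. The place of a pyloric sample between stomach (0) and duodenum (1) was the median share of the distance over genes that differed at least 4-fold. Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 prepared tables and figures.

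Gene lists, 26 in number, were fixed before the data were examined: lipid absorption and lipoprotein assembly, brush border structure and digestive hydrolases, intestinal nutrient and ion transporters, intestinal epithelial transcription factors, gastric epithelium, pyloric and stomach mesenchyme regulators, Hox genes, Hedgehog pathway, Wnt pathway and targets, BMP pathway, Notch pathway, goblet and Paneth cells, enteroendocrine cells, general epithelium, smooth muscle, extracellular matrix and fibroblasts, enteric neurons and glia, cell division, cholesterol synthesis, pancreas, liver, squamous epithelium, mesothelium and spleen, blood and erythroid cells, leukocytes, and endothelium. Lists were tested with camera at its preset correlation of 0.01, and again with an estimated correlation and with fry. Named genes were the 5 largest called rises and falls of each comparison, up to 4 called members of each list (the 2 largest values where fewer than 2 were called), 19 markers, and the 8 genes furthest above or below both neighbours. For tissue and age comparisons the largest rises and falls were limited to genes whose samples did not overlap between the groups, and symbols that are only clone or predicted-gene names were passed over.

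The fit was tested on simulated data with the real design, 18193 genes, and 67, 67 and 66 genes changed by a log2 of 0.5, 1 and 2. A log2 change of 1 was recovered for 82.1% of changed genes between duodenum and stomach, 89.6% between pylorus and stomach and 88.1% between pylorus and duodenum at E14.5. At E16.5 the shares were 92.5%, 91.0% and 91.0%, and with age 89.6% in stomach, 94.0% in pylorus and 71.6% in duodenum. A log2 change of 0.5 was recovered for 26.9%, 40.3% and 38.8% at E14.5, 47.8%, 49.3% and 41.8% at E16.5, and 40.3%, 40.3% and 23.9% with age, in the same order. False calls made up 3.5% to 6.6% of calls. The simulated noise was normal and independent between genes, without outlying pools, in 1 run per comparison. The changes of a tissue difference with age were not simulated. These shares need not hold for the real data.

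Alternatives tried were the mean of a gene's probe sets, all named probe sets, quantile normalization, centring of each array on its median, genes above the median of the gene means, only the groups compared, an intensity trend with a robust prior, the replicate number as a block, a 2-fold threshold for the position, and leaving out each sample in turn. All arrays as separate samples, leaving out 3 doubted arrays, and leaving out each sample for the gene lists, were added after the data were seen. Raw image files were not used here.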

Results

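RNA from the stomach next to the pylorus, from the pylorus and from the duodenum of mouse embryos was compared at E14.5 and E16.5 on 18 arrays. The sample notes give each array as a pool of tissue from many embryos, so the p-values weigh differences against the spread between pools. For each gene this spread was estimated over all 6 groups together, so pools outside a comparison bear on its p-values too. That spread does not show the variation between embryos, and the number of arrays limits the precision of the p-values. The first 2 duodenal arrays of E14.5 differed by less than any other pair of replicates, with an SD of 0.079 against 0.177 to 0.497. Whether they held separate pools or 1 pool hybridized again is not known. They were counted as 1 sample, which left n = 2 in that group and n = 3 in each other group. The median log2 intensity of an array lay between 6.75 and 6.92. Levels are log2 intensities given as mean ± SD. Differences are log2 differences ± SE from limma, and a gene is called higher or lower when its limma adjusted p lies under 0.05 over the 18193 genes tested.

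The transcription factors that mark the intestine, the stomach and the pyloric sphincter separated the 3 tissues at both ages. Cdx2, which sets intestinal identity, stood at 6.09 ± 0.25 in stomach (n = 3), 9.82 ± 0.35 in pylorus (n = 3) and 9.97 ± 0.33 in duodenum (n = 2) at E14.5. It stood at 6.95 ± 0.59, 10.73 ± 0.17 and 10.79 ± 0.04 at E16.5 (n = 3 each). Sox2, a foregut epithelial factor, fell from stomach to duodenum. It stood at 11.83 ± 0.02, 10.03 ± 1.19 and 8.92 ± 0.08 at E14.5 and at 11.22 ± 0.14, 10.19 ± 0.50 and 5.74 ± 0.27 at E16.5. Barx1, a factor of the stomach mesenchyme, was at 12.47 ± 0.16, 11.72 ± 0.58 and 8.48 ± 0.13 at E14.5 and at 11.40 ± 0.35, 10.53 ± 0.23 and 6.98 ± 0.11 at E16.5. Nkx2-5 and Gata3, which act in the mesenchyme of the forming sphincter, were highest in the pylorus. Nkx2-5 stood there at 9.89 ± 0.50, against 7.39 ± 0.06 in stomach and 7.20 ± 0.14 in duodenum at E14.5. Gata3 was at 8.54 ± 0.92 against 5.78 ± 0.13 and 5.24 ± 0.31. In the pylorus Cdx2 lay near its duodenal level at both ages, Barx1 lay above its duodenal level at both ages, and Sox2 lay above it at E16.5. Cdh1, an epithelial adhesion gene, differed by no more than 0.29 ± 0.13 between tissues at either age and was not called between tissues.

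**Figure D1:**
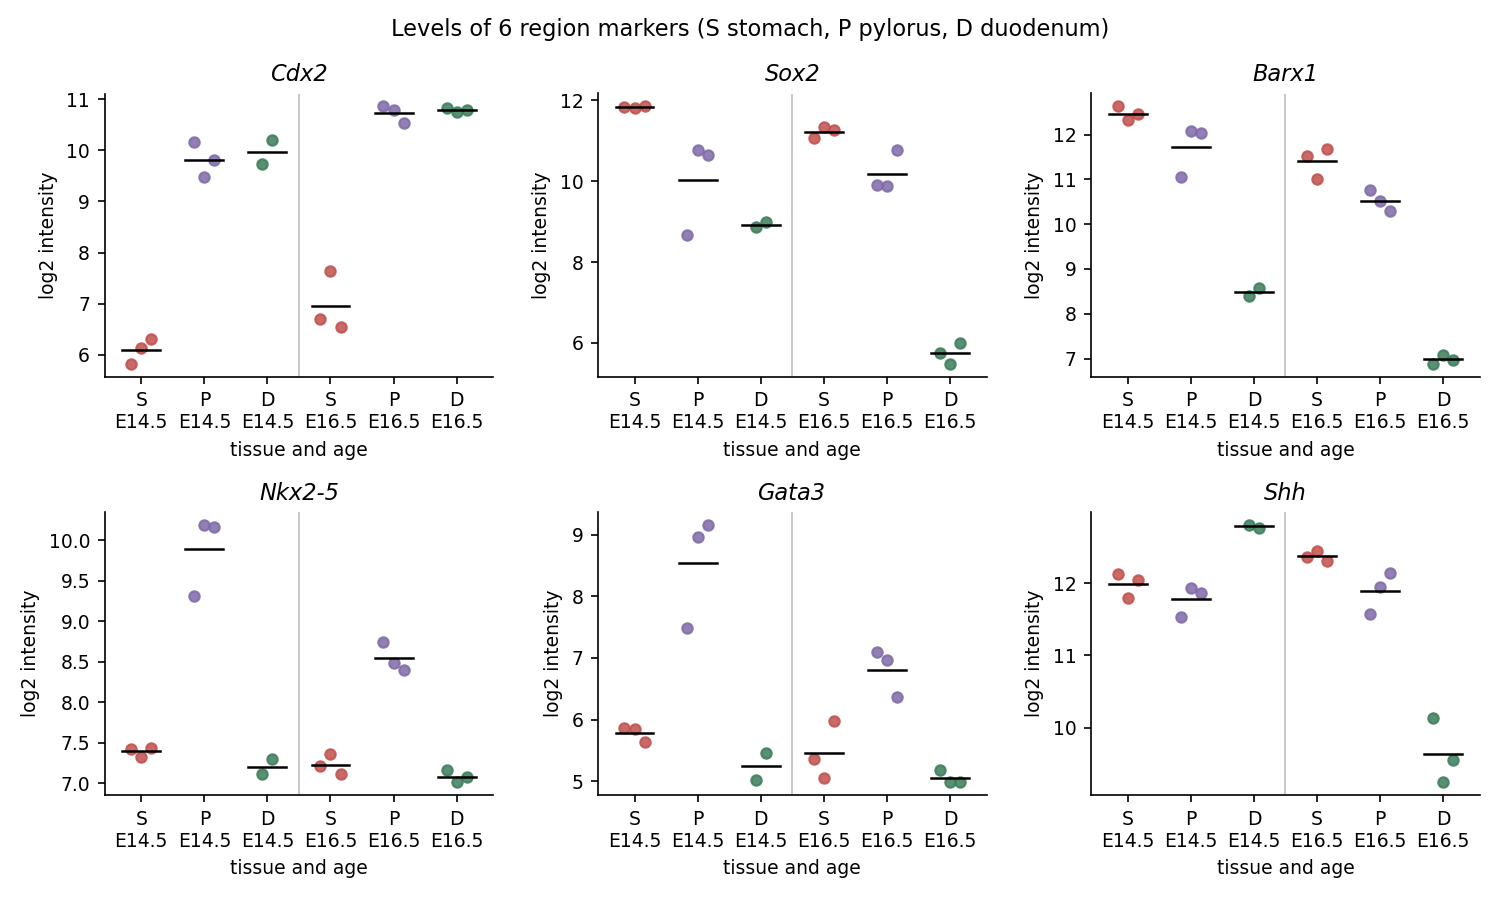
Log2 intensity of Cdx2, Sox2, Barx1, Nkx2-5, Gata3 and Shh (vertical axes) in stomach (S), pylorus (P) and duodenum (D) at E14.5 and E16.5, with each point 1 sample and each line the group mean. Nkx2-5 is highest in the pylorus at both ages, at 9.89 and 8.55, and Shh in the duodenum falls from 12.79 to 9.64.

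At E14.5 the duodenum (n = 2) differed from the stomach (n = 3) in its intestinal absorptive genes, its transcription factors and its mesenchyme. Cps1, a urea cycle enzyme of liver and gut, was higher in duodenum by 6.14 ± 0.79, the galectin Lgals2 by 5.54 ± 0.31, the intestinal cadherin Cdh17 by 5.46 ± 0.44 and the fatty acid binding gene Fabp2 by 4.96 ± 0.76 (limma adjusted p from 4.22e-08 to 0.000796). The intestinal regulators Isx, Prdm1, Onecut2 and Cdx2 were higher by 4.83 ± 0.24, 4.25 ± 0.40, 4.06 ± 0.20 and 3.88 ± 0.27. Among the largest falls were those of Bpifb1, Cldn18, Cxcl15 and the gastric protease Cym, at -5.06 ± 0.78, -4.63 ± 0.58, -4.38 ± 0.23 and -4.16 ± 0.48. Of 25 mesenchyme regulators 7 were lower and 4 higher (8 and 4 adjusted over the list alone), with a median of -0.33. The largest of these differences were falls, with Barx1 at -3.98 ± 0.26, Six2 at -2.95 ± 0.23, Isl1 at -2.62 ± 0.37 and Bmpr1b at -2.53 ± 0.34. Of 28 Wnt genes 5 were higher and 2 lower (6 and 4 adjusted over the list alone), and the list was not called (median -0.13, adjusted p = 0.549). Among them Sfrp5 was higher by 3.75 ± 0.18 and Rspo3 by 1.29 ± 0.21, and Wnt5a differed by -1.27 ± 0.15. The BMP antagonist Fst differed by -3.37 ± 0.42. The endocrine genes Neurog3 and Cck were higher by 2.60 ± 0.30 and 1.95 ± 0.39, and the goblet cell peptide Tff3 by 3.49 ± 0.54.

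By gene list, 11 of 25 brush border and hydrolase genes were higher in duodenum at E14.5 (12 adjusted over the list alone). So were 5 of 20 lipid absorption genes (6 adjusted over the list alone), 8 of 26 transporters, with 1 lower (9 and 1 adjusted over the list alone), and 10 of 20 intestinal transcription factors (12 higher and 2 lower adjusted over the list alone). Of 26 gastric epithelial genes 14 were lower (19 adjusted over the list alone), with a median of -1.36. Smooth muscle genes had a median of 0.46, with Ppp1r14a higher by 1.52 ± 0.24 and Hspb6 by 1.47 ± 0.32. The pancreas list, with Ptf1a higher by 1.72 ± 0.19, the enteroendocrine list and the squamous list were called too, at medians of 0.49, 0.52 and -0.28. The duodenal samples stood apart in the absorptive lists, with mean lipid levels of 9.78 in sample 1 and 8.45 in replicate 3. Without sample 1 the medians of the lipid, brush border and transporter lists went from 1.27, 1.51 and 0.78 to 0.47, 0.92 and 0.37, with 1, 5 and 3 genes higher, and that of the pancreas list rose to 0.74. With an estimated correlation none of the 10 lists called in this comparison passed (adjusted p = 0.0696 to 0.524 with an estimated correlation). In all, 1144 genes were called, 703 higher and 441 lower, and 261 and 231 of these differed at least 2-fold. The count fell to 430 without duodenal sample 1, to 577 without duodenal replicate 3, and to 709 and 746 without stomach replicates 1 and 2. It was 2638 when only the samples of these groups were fitted.

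The pylorus at E14.5 (n = 3) was higher than the stomach in a part of the intestinal genes and in the sphincter genes Gata3 and Nkx2-5. Cps1 was higher by 5.47 ± 0.71, Cdh17 by 5.20 ± 0.39, Lgals2 by 5.20 ± 0.27, Fabp1 by 5.03 ± 0.90 and the mucosal scavenger receptor gene Dmbt1 by 4.87 ± 0.61 (limma adjusted p from 3.36e-08 to 0.00442). Isx, Cdx2, Onecut2 and Prdm1 were higher by 4.12 ± 0.21, 3.73 ± 0.24, 3.43 ± 0.18 and 2.88 ± 0.35. In the mesenchyme, the BMP antagonist Grem1 was higher by 2.84 ± 0.32, Gata3 by 2.76 ± 0.35, Nkx2-5 by 2.49 ± 0.18 and Nkx2-3 by 1.70 ± 0.29. Cxcl15, Aqp4, Cym, Gsdmc2 and Bpifb1 differed by -3.77 ± 0.20, -3.33 ± 0.13, -3.33 ± 0.43, -3.15 ± 0.37 and -2.99 ± 0.70. Sox2 differed by -1.81 ± 0.40. Six2 (0.15 ± 0.21) and Barx1 (-0.74 ± 0.23) were not called, at adjusted p of 0.830 and 0.101. In the enteric neuron and glia list Tubb3 (-0.76 ± 0.15), the glial gene Fabp7 (-0.62 ± 0.16) and Syt1 (-0.59 ± 0.14) were lower. Ptprc, a white blood cell gene, was higher by 1.05 ± 0.13.

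Of the intestinal lists, 12 of 20 transcription factors (14 adjusted over the list alone), 12 of 25 brush border genes (17 adjusted over the list alone), 8 of 26 transporters (15 adjusted over the list alone) and 7 of 20 lipid genes (13 adjusted over the list alone) were higher in the pylorus than in the stomach at E14.5. Against them, 1 transcription factor and 1 transporter were lower (2 and 1 adjusted over the list alone). One pyloric pool stood apart in these lists. Replicate 1 had mean levels of 10.58 for lipid genes (8.34 and 9.11 in the other pools), 9.44 for brush border genes (7.41 and 8.14) and 8.34 for transporters (6.84 and 7.26). Without it the medians of these lists went from 1.39, 1.75 and 1.22 to 0.75, 1.14 and 0.60, with 5, 7 and 7 genes higher. Of 26 gastric genes 7 were lower (13 adjusted over the list alone), and of 18 enteric neuron and glia genes 4 were lower (10 adjusted over the list alone). The transcription factor list (adjusted p = 0.0148 with an estimated correlation) and the enteric neuron and glia list (adjusted p = 0.0148 with an estimated correlation) kept their calls, and the other 11 called lists did not (adjusted p = 0.0588 to 0.7 with an estimated correlation). Some markers of other tissues were higher as well, though none of these lists kept its call: the erythroid list had a median of 0.94 with 3 of 12 genes called (8 adjusted over the list alone), the leukocyte list 0.53 with 4 of 15 (12 adjusted over the list alone), and the liver list 0.81 with Cps1 alone of 16 (2 higher and 1 lower adjusted over the list alone). Cps1 is also a gut gene and was higher in the duodenum too, so its rise does not mark liver. The 649 genes called divided into 377 higher and 272 lower, 192 and 90 of them at least 2-fold. Without stomach replicate 1, 2 or 3 the count was 351, 375 or 402, and with only these groups fitted it was 375.

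Between pylorus and duodenum at E14.5 the differences lay in gastric and sphincter mesenchyme, in gastric epithelium and in nerve cells, and 154 genes were called. In the pylorus Gata3 was higher by 3.30 ± 0.39, Barx1 by 3.24 ± 0.26, Anxa10 by 3.14 ± 0.60, Six2 by 3.10 ± 0.23 and Cldn18 by 2.89 ± 0.58 (limma adjusted p from 6.78e-06 to 0.0271). Nkx2-5 was higher by 2.68 ± 0.20, the mucin Muc1 by 2.18 ± 0.37 and the antral hormone Gast by 1.89 ± 0.31. Cbln2, Crp, Slitrk4, Mreg and Thbs4 differed by -1.96 ± 0.17, -1.77 ± 0.20, -1.71 ± 0.13, -1.69 ± 0.26 and -1.51 ± 0.22. The Wnt agonists Rspo1, Rspo2 and Rspo3 were lower at -1.18 ± 0.24, -1.16 ± 0.26 and -1.13 ± 0.21, and Shh, the epithelial Hedgehog ligand, at -1.01 ± 0.22. The neuropeptide Vip differed by -1.21 ± 0.18, Syt1 by -1.05 ± 0.16, Fabp7 by -1.04 ± 0.18 and Snap25 by -0.97 ± 0.16. Cdx2 (-0.15 ± 0.27, adjusted p = 0.992) and Vil1 (-0.23 ± 0.33, adjusted p = 0.977) were not called.

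Of 18 enteric neuron and glia genes 6 were lower in the pylorus than in the duodenum at E14.5 and none higher (13 lower adjusted over the list alone), and this list kept its call (adjusted p = 0.000406 with an estimated correlation). Of 26 gastric genes 5 were higher (10 adjusted over the list alone; adjusted p = 0.0843 with an estimated correlation) and of 25 mesenchyme regulators 6 (8 higher and 2 lower adjusted over the list alone; adjusted p = 0.115 with an estimated correlation). No gene of the lipid, brush border, transporter or intestinal transcription factor lists was called, at medians of 0.13, -0.08, 0.03 and -0.11 (0, 1, 0 and 6 adjusted over the list alone, the 6 being 2 higher and 4 lower). These values near 0 moved with single samples. Without pyloric replicate 1 the medians were -0.29, -0.53, -0.25 and -0.35 and all 4 lists were called lower. Without pyloric replicate 2 they were 0.64, 0.35, 0.29 and 0.00, and without pyloric replicate 3 0.33, -0.03, 0.19 and -0.07. Without duodenal sample 1 they were 0.75, 0.37, 0.36 and 0.02, and without duodenal replicate 3 they were -0.19, -0.45, -0.16 and -0.23. Goblet and Paneth cell genes were called as a list with a median of -0.04 and a mean of 0.09, the single called list whose median and test differed in sign (adjusted p = 0.534 with an estimated correlation). Its median was 0.31 without duodenal sample 1, and without pyloric replicate 1 or duodenal replicate 3 it was not called (-0.23 and -0.33). In all, 15 of the 16 lists called here lost their call (adjusted p = 0.0843 to 0.734 with an estimated correlation). Of the 154 genes 51 were higher and 103 lower, with 43 and 38 at least 2-fold. Without pyloric replicate 1, 2 or 3 the count was 420, 102 or 65, and without duodenal sample 1 or replicate 3 it was 68 or 14. Fitting only these groups left 0 genes by limma, with 1327 at an unadjusted p under 0.05.

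Genes that stood higher in the pylorus than in both neighbours at E14.5 numbered 3: Gata3, Nkx2-5 and the cartilage gene Cnmd, which was higher than in stomach by 2.10 ± 0.29 and than in duodenum by 2.17 ± 0.32. Lower than in both were 17 genes, among them Synpr (-1.33 ± 0.19 and -0.99 ± 0.21), Tubb3 (-0.76 ± 0.15 and -0.83 ± 0.17), Cdh19 (-0.65 ± 0.16 and -0.83 ± 0.18) and Chrna3 (-0.65 ± 0.14 and -0.79 ± 0.16). Mreg (-1.74 ± 0.24 and -1.69 ± 0.26) and Rspo1 (-0.84 ± 0.21 and -1.18 ± 0.24) were lower too. Without pyloric replicate 1 the number higher than in both was 52, and without duodenal sample 1 it was 6.

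By E16.5 the duodenum and the stomach (n = 3 each) differed in 8387 genes, and the absorptive program was far apart. The brush border peptidases Mep1b and Mme were higher in duodenum by 6.82 ± 0.51 and 6.69 ± 0.51, the vitamin B12 receptor gene Cubn by 6.57 ± 0.71, Ugt2b5 by 6.77 ± 0.78 and the antimicrobial peptide Leap2 by 6.53 ± 0.28 (limma adjusted p from 5.10e-10 to 3.64e-06). The transporters Slc26a3 and Slc2a2 were higher by 6.43 ± 0.77 and 6.32 ± 0.41. The apolipoproteins Apob and Apoc2 were higher by 5.63 ± 0.51 and 5.47 ± 0.54, the hormones Cck and Gip by 5.24 ± 0.35 and 4.02 ± 0.23, and Tff3 by 4.20 ± 0.49. In the stomach direction, Gsdmc2, Bpifb1, Krt13, Mal and the acid pump subunit Atp4a were at -6.84 ± 0.37, -6.81 ± 0.70, -6.74 ± 0.29, -6.17 ± 0.64 and -6.05 ± 0.22. Gkn1 was at -5.85 ± 0.44, Sox2 at -5.48 ± 0.40 and Barx1 at -4.42 ± 0.23. Shh differed by -2.74 ± 0.19, its target Gli1 by -1.61 ± 0.26, Wnt5a by -2.13 ± 0.14, Notch3 by -1.93 ± 0.26, the BMP target Id1 by -1.94 ± 0.22 and the matrix gene Eln by -2.48 ± 0.20.

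All 20 lipid genes (20 adjusted over the list alone), 24 of 25 brush border genes (25 adjusted over the list alone) and 23 of 26 transporters, with 2 lower (23 and 2 adjusted over the list alone), were higher in duodenum at E16.5, with medians of 3.42, 4.93 and 4.32. In turn 24 of 26 gastric genes were lower (24 adjusted over the list alone) with a median of -3.92. Called members were lower for 19 of 21 matrix and fibroblast genes, 21 of 24 cell division genes, 11 of 13 Hedgehog genes, 15 of 28 Wnt genes (1 higher), 12 of 19 Notch genes (3 higher), 8 of 19 BMP genes (1 higher), 12 of 19 smooth muscle genes and 10 of 24 Hox genes (19, 23, 11, 16, 13, 8, 12 and 10 adjusted over the list alone). Stomach replicate 3 stood apart for smooth muscle, at a mean of 11.68 against 11.03 and 10.99, and it and duodenal replicate 1 carried immediate-early and heat-shock genes at 11.33 and 11.28. Without stomach replicate 3 the smooth muscle median went from -0.57 to -0.38 with 9 genes lower and 1 higher, and the Hox median from -0.23 to -0.13 with 7 lower. Without stomach replicate 1 the Hox median was -0.36. Squamous keratin genes were lower in duodenum for 11 of 12 (11 adjusted over the list alone), with Krt4 at -5.68 ± 0.20. The 19 lists called in this comparison lost their call with an estimated correlation (adjusted p = 0.107 to 0.447 with an estimated correlation). Goblet and Paneth cell (median 0.92), cholesterol synthesis (0.31), pancreas (0.46), liver (-0.11, mean 0.23), erythroid (-0.14), leukocyte (0.29) and endothelial (-0.10) lists were not called. Of the 8387 genes 4152 were higher and 4235 lower, 1499 and 1420 at least 2-fold. The share higher was 49.5% as deposited, 44.6% after quantile normalization and 54.0% with each array centred on its median.

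The pylorus at E16.5 kept intestinal gene levels well above those of the stomach and had lower levels of the squamous and acid-secreting genes. Reg1, a regenerating-protein gene, was higher than in stomach by 6.83 ± 0.73, Ugt2b5 by 6.00 ± 0.78, Mme by 5.28 ± 0.51, ccdc198 by 5.13 ± 0.32 and Slc26a3 by 5.09 ± 0.77 (limma adjusted p from 5.97e-08 to 0.000283). Isx and Cdx2 were higher by 4.04 ± 0.21 and 3.78 ± 0.24, Cck by 4.76 ± 0.35, Gip by 3.51 ± 0.23, Tff3 by 4.31 ± 0.49 and Muc2 by 3.40 ± 0.43. Krt13, Krtdap, Atp4a, Krt4 and Atp4b were lower at -5.46 ± 0.29, -5.42 ± 0.41, -5.40 ± 0.22, -4.79 ± 0.20 and -4.49 ± 0.16. Intrinsic factor, Cblif, was at -3.74 ± 0.19. Grem1 was higher by 2.29 ± 0.32. Pitx1 and Irx3 differed by -1.88 ± 0.31 and -1.83 ± 0.36 and Hoxc5 by -1.78 ± 0.37. Sox2 (-1.04 ± 0.40, adjusted p = 0.0799) and Gkn1 (-1.25 ± 0.44, adjusted p = 0.0573) were not called.

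Higher in pylorus than in stomach at E16.5 were 18 of 20 lipid genes, 20 of 25 brush border genes, 22 of 26 transporters and 15 of 20 intestinal transcription factors (18, 20, 22 and 15 adjusted over the list alone), with 1 transporter and 2 transcription factors lower (1 and 2 adjusted over the list alone). Higher too were 9 of 15 goblet and Paneth cell genes and 11 of 21 enteroendocrine genes (9 and 12 adjusted over the list alone), with 1 goblet or Paneth cell gene lower (2 adjusted over the list alone). Lower were 11 of 12 squamous genes (11 adjusted over the list alone), 11 of 26 gastric genes with 2 higher (14 and 2 adjusted over the list alone) and 11 of 21 matrix genes (15 adjusted over the list alone). None of the 20 called lists kept its call (adjusted p = 0.0680 to 0.567 with an estimated correlation). Of 16 liver genes 5 were higher and 1 lower (5 and 1 adjusted over the list alone), with a median of 0.90 and Ambp at 3.12 ± 0.32. Of 12 erythroid genes 4 were higher (4 adjusted over the list alone), with a median of 0.61 and Alas2 at 1.53 ± 0.37. Without stomach replicate 3 or pyloric replicate 1 the liver median was 0.53 or 0.50 and the erythroid list was not called (0.46 or 0.36). Stomach replicate 3 carried a mean level of 11.33 for immediate-early and heat-shock genes, against 9.12 and 8.75 in the other stomach pools of that age. The 3894 called genes divided into 2263 higher and 1631 lower, 614 and 290 at least 2-fold. The share higher was 58.1% and became 43.1% after quantile normalization, and the count was 2482 without pyloric replicate 2.

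Set against the duodenum, the pylorus at E16.5 was lower in many absorptive genes and higher in many gastric epithelial genes and mesenchyme regulators. The myelin and lymphocyte gene Mal was higher by 5.73 ± 0.64, Sptssb by 5.38 ± 0.49, Bpifb1 by 5.28 ± 0.70, Cldn18 by 5.11 ± 0.52 and Anxa10 by 4.83 ± 0.54 (limma adjusted p from 2.32e-06 to 4.77e-05). Gkn2, Gkn1 and Sox2 were higher by 4.76 ± 0.43, 4.60 ± 0.44 and 4.44 ± 0.40. Barx1 was higher by 3.55 ± 0.23, Isl1 by 3.15 ± 0.33, Six2 by 2.36 ± 0.21 and Shh by 2.25 ± 0.19. Meltf, Naaladl1, the bile salt pump Abcb11, Bst1 and Paqr9 differed by -4.10 ± 0.44, -3.83 ± 0.17, -3.59 ± 0.30, -3.58 ± 0.42 and -3.56 ± 0.24. The transporters Abcc2 and Slc9a3 differed by -3.09 ± 0.51 and -2.91 ± 0.31. Cdx2 did not differ by more than its error (-0.06 ± 0.24), whereas Isx and Creb3l3 differed by -0.83 ± 0.21 and -1.37 ± 0.35. The nerve genes Gfra1, Stmn2 and Hand2 were higher by 1.81 ± 0.25, 1.58 ± 0.22 and 1.58 ± 0.23, the mitotic kinesin Kif20a by 1.26 ± 0.17 and the collagen Col12a1 by 1.97 ± 0.23.

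In the lists, 21 of 26 gastric genes, 22 of 24 cell division genes, 14 of 21 matrix genes, 14 of 25 mesenchyme regulators, 8 of 13 Hedgehog genes, 13 of 28 Wnt genes, 10 of 20 general epithelial genes and 7 of 18 enteric neuron and glia genes were higher in pylorus than in duodenum at E16.5 (22, 22, 15, 14, 9, 13, 11 and 7 adjusted over the list alone). Called the other way were 2 Wnt genes, 3 general epithelial genes, 1 enteric neuron or glia gene and 1 mesenchyme regulator (2, 3, 1 and 2 adjusted over the list alone). Lower were 17 of 25 brush border genes, 18 of 26 transporters, 12 of 20 lipid genes and 10 of 20 intestinal transcription factors (19, 19, 12 and 11 adjusted over the list alone). In these lists 2 transporters and 2 transcription factors were higher (2 and 2 adjusted over the list alone). Mesothelial and spleen genes were higher for 7 of 10, liver genes for 8 of 16 and erythroid genes for 6 of 12 (7, 9 and 6 adjusted over the list alone). The liver list was not called without pyloric replicate 1, nor the erythroid list without pyloric replicate 1 or 2 or duodenal replicate 2. Smooth muscle (3 of 19 higher) and endothelium (2 of 16 lower) were not called as lists (2 and 1 adjusted over the list alone). No list called here kept its call (adjusted p = 0.362 to 0.547 with an estimated correlation). Duodenal replicate 1 had a mean level of 11.28 for immediate-early and heat-shock genes, against 9.05 and 9.22 in the other duodenal pools. In total 6731 genes were called, 3564 higher and 3167 lower, 859 and 699 at least 2-fold. The share higher was 52.9% as deposited, 49.3% after quantile normalization and 45.8% with each array centred on its median.

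At E16.5 the pylorus stood higher than both neighbours for 266 genes and lower for 163. Nepn, a matrix proteoglycan gene, led with 4.09 ± 0.35 over stomach and 4.07 ± 0.35 over duodenum. After it came the embryonic globin Hbb-y (2.26 ± 0.69 and 2.74 ± 0.69), the cartilage collagen Col9a1 (2.21 ± 0.37 and 3.38 ± 0.37), the red cell anion exchanger Slc4a1 (2.04 ± 0.57 and 2.40 ± 0.57) and the uroplakin Upk1a (2.29 ± 0.13 and 2.03 ± 0.13). Grem1 (2.29 ± 0.32 over stomach), Gata3 (1.35 ± 0.35 and 1.76 ± 0.35) and Nkx2-5 (1.32 ± 0.18 and 1.46 ± 0.18) were among them. So was Ambp of the liver list (3.12 ± 0.32 and 1.26 ± 0.32). Pdia2 (-2.51 ± 0.33 and -1.53 ± 0.33), Sectm1b (-1.24 ± 0.36 and -1.59 ± 0.36), the hemidesmosome integrin Itgb4 (-0.98 ± 0.25 and -1.25 ± 0.25) and the Wnt inhibitor Rnf43 (-1.10 ± 0.28 and -0.84 ± 0.28) stood lower than both. The number higher than both was 149 and 150 without stomach replicates 1 and 3, 134 and 132 without pyloric replicates 1 and 2, and 162 after quantile normalization. Erythroid and liver genes varied together between pools, and with the liver level as a covariate 32 genes were called.

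**Figure D2:**
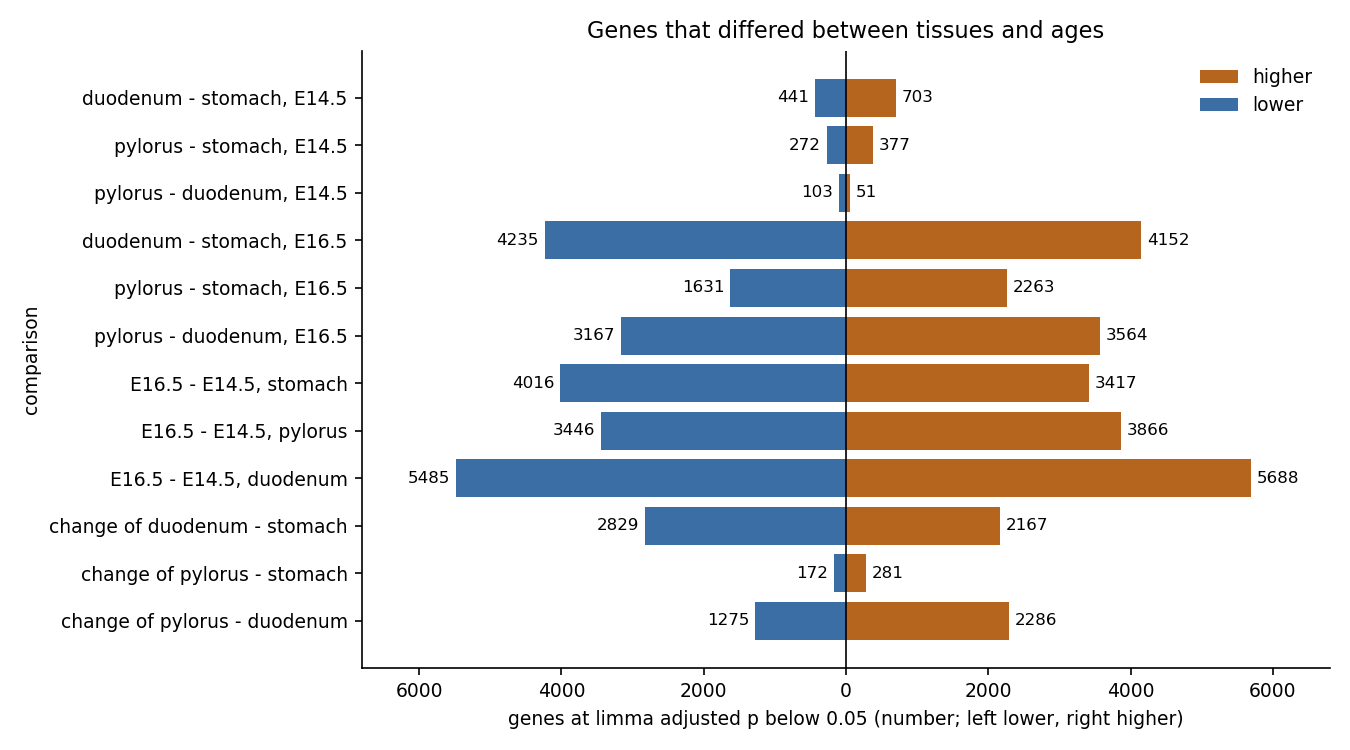
Number of genes called higher (right) and lower (left) at limma adjusted p under 0.05 in each comparison of tissues, ages and changes of a difference with age (vertical axis), with bar labels giving the counts. The pylorus minus duodenum difference at E14.5 has the fewest genes, 51 and 103, and the change of the duodenum with age the most, 5688 and 5485.

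The place of the pylorus on the axis from stomach (0) to duodenum (1) was measured over 914 genes that differed at least 4-fold between these tissues at E16.5. At E16.5 the pyloric samples lay at 0.498, 0.535 and 0.424 (mean 0.486 ± 0.056, n = 3). Genes higher in duodenum placed them at 0.548 ± 0.067 (582 genes) and genes higher in stomach at 0.321 ± 0.065 (332 genes). On the log2 scale a mix of both tissues also places the former genes higher than the latter, so this split does not tell how far each set had moved. At E14.5 the same genes gave 1.386, 0.389 and 0.628 (mean 0.801 ± 0.520, n = 3), a spread set by replicate 1. A fit without it, with the 4-fold genes chosen anew, gave a mean of 0.507. Split in the same way with replicate 1, the 914 genes gave 0.915 ± 0.640 and 0.619 ± 0.361. Over the 161 genes that differed 4-fold at E14.5 itself the mean was 0.725 ± 0.256. Replicate 1 of the E14.5 pylorus also carried the lipid absorption genes at a mean of 10.58, against 8.34 and 9.11 in the other pools of that group.

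**Figure D3:**
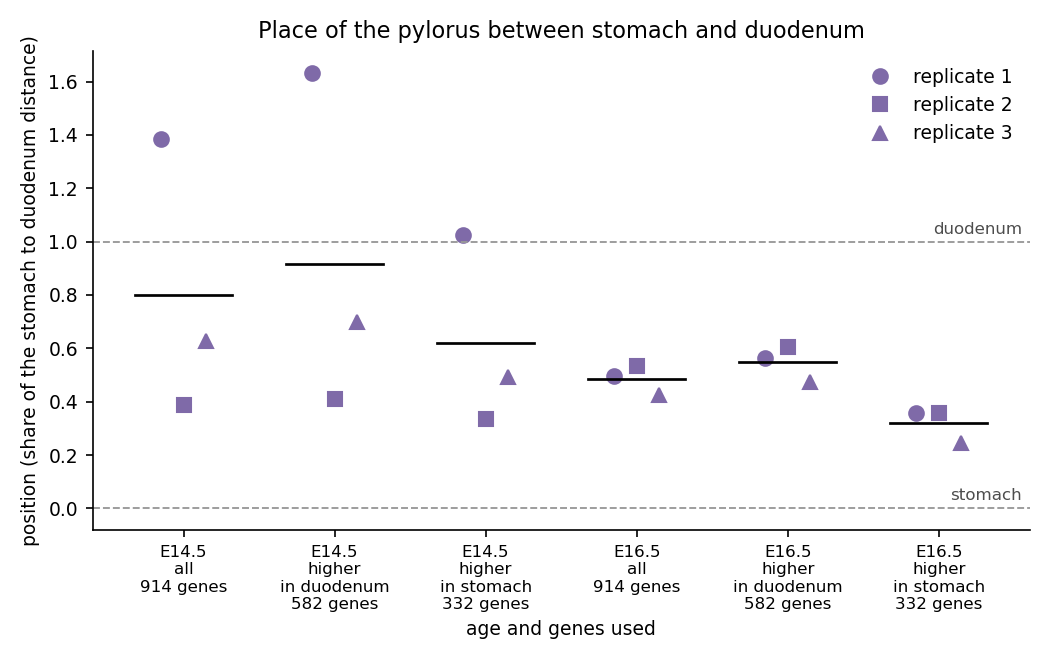
Position of each pyloric sample (points, 1 per replicate; lines, means) as the median share of the distance from stomach (0) to duodenum (1), for all 914 genes and for those higher in duodenum or in stomach. At E16.5 the samples lie between 0.424 and 0.535 over all genes, and at E14.5 between 0.389 and 1.386.

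From E14.5 to E16.5 the stomach (n = 3 per age) gained gastric, squamous and some absorptive genes. The gastrokines Gkn1 and Gkn2 rose by 6.35 ± 0.44 and 6.23 ± 0.43, Dmbt1 by 6.12 ± 0.61, Dmkn by 6.01 ± 0.35, Krtdap by 5.93 ± 0.41 and the acid pump gene Atp4a by 5.74 ± 0.22 (limma adjusted p from 9.25e-10 to 4.53e-06). Krt13 and Krt4 rose by 5.93 ± 0.29 and 4.89 ± 0.20, Fabp1 by 5.34 ± 0.90, the hormone Ghrl by 3.24 ± 0.45, Wnt4 by 2.66 ± 0.19 and Bmp2 by 2.41 ± 0.24. The embryonic globins Hbb-y, Hba-x and Hbb-bh1 changed by -6.74 ± 0.69, -5.01 ± 0.33 and -4.20 ± 0.41. Nepn changed by -4.67 ± 0.35, Sox11 by -2.57 ± 0.34, Gfra1 by -1.93 ± 0.25 and the Hedgehog effector Gli3 by -1.35 ± 0.18. Higher were 20 of 26 gastric genes, 11 of 12 squamous genes, 14 of 20 lipid genes and 10 of 20 general epithelial genes (22, 12, 14 and 10 adjusted over the list alone). Stomach replicate 2 of E16.5 had a mean lipid level of 10.18, against 9.14 and 9.48 in replicates 1 and 3. Cdx2 stood there at 7.63, against 6.69 and 6.54. The E14.5 stomach samples had mean lipid levels of 7.38 to 7.62. What set replicate 2 apart was not tested. Lower were 22 of 24 cell division genes, 12 of 18 enteric neuron and glia genes and 11 of 24 Hox genes (22, 12 and 11 adjusted over the list alone). Called the other way were 2 general epithelial, 3 enteric neuron and glia and 3 Hox genes (2, 3 and 4 adjusted over the list alone). The Hox list was not called without stomach replicate 1 or 2 of either age. None of the 14 called lists kept its call (adjusted p = 0.148 to 0.730 with an estimated correlation). The 7433 genes called were 3417 higher and 4016 lower, 877 and 529 at least 2-fold. The share higher was 46.0% as deposited, 57.8% after quantile normalization and 59.0% with each array centred on its median.

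The pylorus (n = 3 per age) gained absorptive and gastric genes together, and its sphincter genes Gata3 and Nkx2-5 fell. Reg1 rose by 6.41 ± 0.73, lactase, Lct, by 5.66 ± 0.97, Sult1c2 by 5.60 ± 0.32, Smcp by 5.47 ± 0.29 and Clca4b by 5.38 ± 0.42 (limma adjusted p from 2.05e-08 to 0.000425). Pga5 and Gkn2 rose by 5.34 ± 0.48 and 5.09 ± 0.43 and the hormones Gip and Sst by 3.94 ± 0.23 and 3.64 ± 0.27. Gata3 changed by -1.73 ± 0.35, Nkx2-5 by -1.34 ± 0.18, Sfrp1 by -1.40 ± 0.12, Rspo3 by -1.61 ± 0.19 and Hba-x by -4.98 ± 0.33. Higher were 24 of 26 transporters, 20 of 25 brush border genes, 21 of 26 gastric genes, 14 of 21 enteroendocrine genes and 11 of 15 goblet and Paneth cell genes (24, 21, 22, 15 and 12 adjusted over the list alone, with 1 enteroendocrine gene lower adjusted over the list alone). Lower were 23 of 24 cell division genes, 12 of 25 mesenchyme regulators, 8 of 13 Hedgehog genes and 8 of 16 endothelial genes (24, 13, 9 and 10 adjusted over the list alone), with Tie1 at -1.34 ± 0.28. None of the 18 called lists kept its call (adjusted p = 0.181 to 0.579 with an estimated correlation). Of the 7312 called genes 3866 were higher and 3446 lower, 1021 and 404 at least 2-fold, and the share higher was 52.9%, or 65.8% with each array centred on its median.

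The duodenum (n = 2 at E14.5 and n = 3 at E16.5) changed most with age, in 11173 genes, with 5688 higher and 5485 lower and 1756 and 2418 at least 2-fold. Meltf rose by 7.88 ± 0.49, Leap2 by 7.52 ± 0.31, Mep1b by 7.22 ± 0.57, Lct by 7.15 ± 1.09 and Fbp1 by 6.95 ± 0.40 (limma adjusted p from 1.76e-09 to 4.65e-05). The E14.5 samples differed from each other, with Lct at 8.93 in sample 1 and 5.38 in replicate 3. Their mean lipid levels were 9.78 and 8.45. Apoc2 rose by 6.63 ± 0.60, Slc26a3 by 5.84 ± 0.86, Creb3l3, a lipid-regulating factor, by 4.82 ± 0.40 and Gip by 4.53 ± 0.26. Hbb-y, Hba-x, Hbb-bh1, the tight junction gene Cldn6 and Zfhx4 changed by -7.27 ± 0.77, -6.09 ± 0.37, -4.74 ± 0.46, -4.25 ± 0.39 and -3.75 ± 0.33. Shh changed by -3.15 ± 0.22 and Sox2 by -3.18 ± 0.45, Hand2 by -2.85 ± 0.25, Kif20a by -2.45 ± 0.19, Dkk2 by -2.73 ± 0.22 and Hoxb3 by -2.57 ± 0.20. All 20 lipid genes, all 25 brush border genes and 24 of 26 transporters were higher (20, 25 and 25 adjusted over the list alone). All 24 cell division genes, 19 of 21 matrix genes, 15 of 18 enteric neuron and glia genes, 14 of 19 smooth muscle genes, 14 of 28 Wnt genes and 9 of 13 Hedgehog genes were lower (24, 19, 15, 15, 14 and 9 adjusted over the list alone). Against them, 1 matrix gene, 1 enteric neuron or glia gene and 2 Wnt genes were higher (1, 1 and 2 adjusted over the list alone, and 1 Hedgehog gene). The enteric neuron and glia list, with a median of -1.80, kept its call (adjusted p = 0.0228 with an estimated correlation), and the other 16 called lists lost theirs (adjusted p = 0.338 to 0.572 with an estimated correlation). Over all genes the median change with age was 0.043, 0.067 and 0.088 in stomach, pylorus and duodenum, and 0.120, 0.143 and 0.167 with each array centred on its median.

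**Figure D4:**
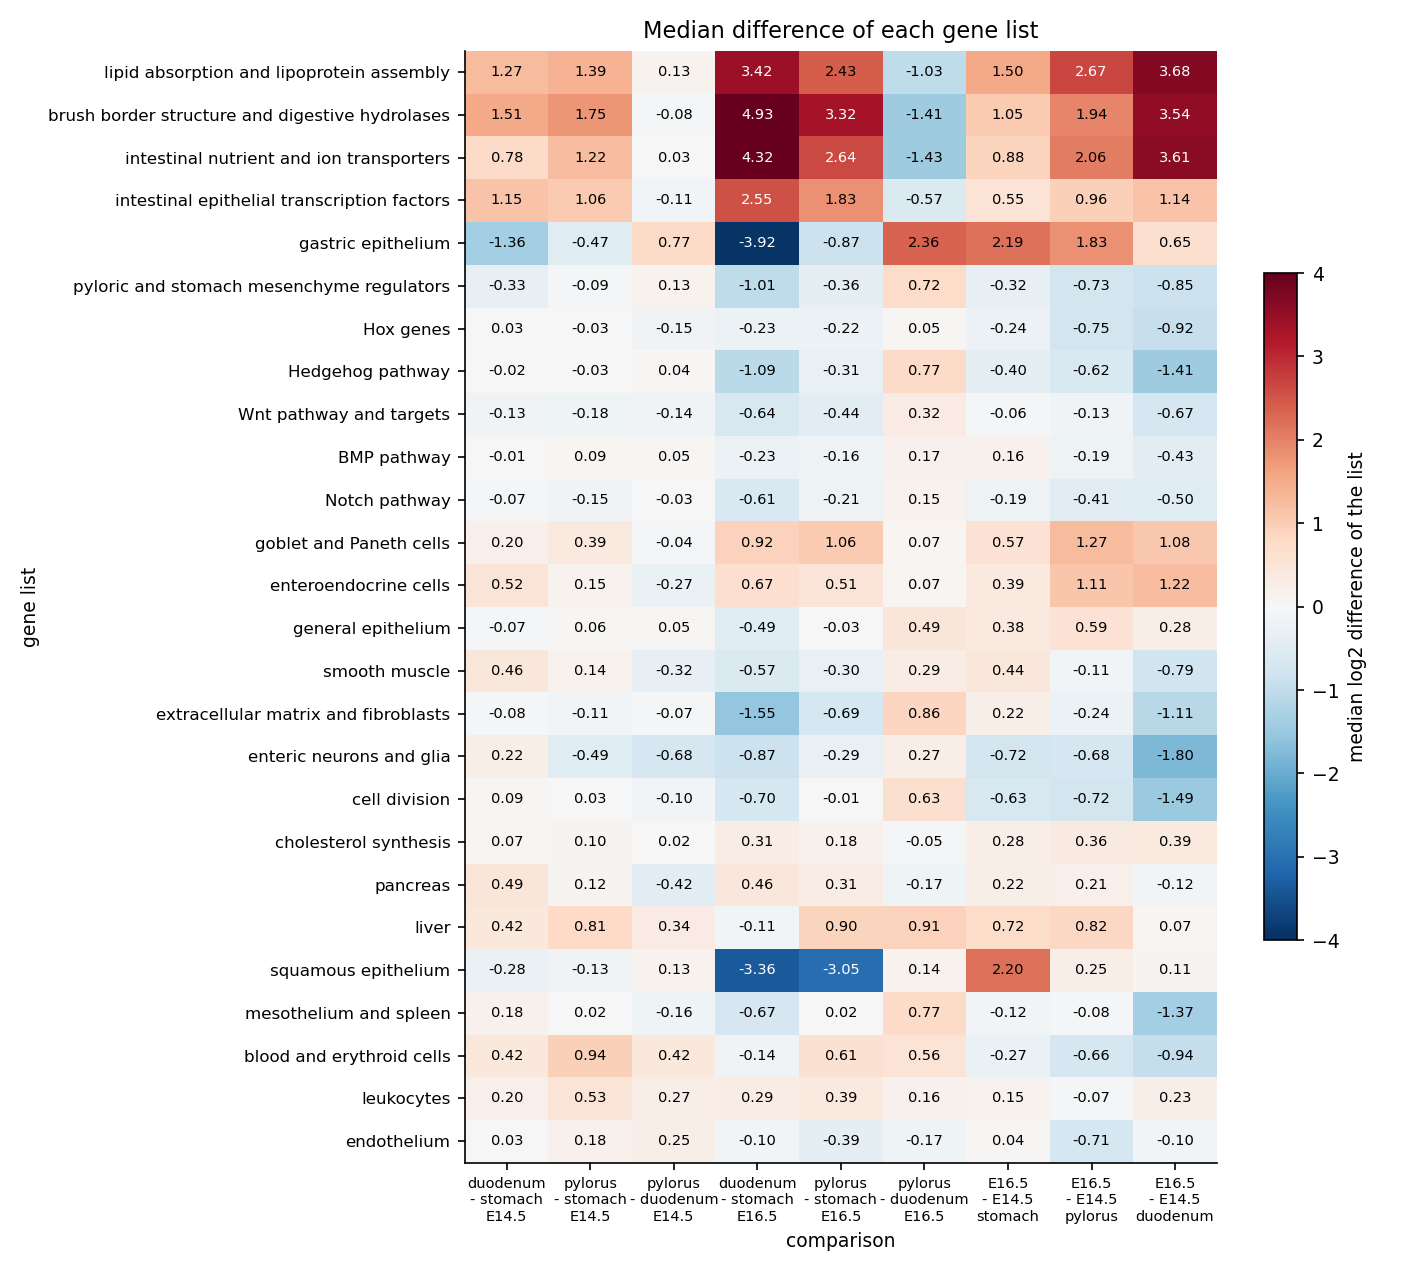
Median log2 difference (color and printed value) of the 26 gene lists (vertical axis) in the comparisons of tissues and ages (horizontal axis). The brush border list reaches 4.93 between duodenum and stomach at E16.5, against 1.51 at E14.5, and the enteric neuron and glia list falls by 1.80 in the duodenum with age.

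The difference between duodenum and stomach changed from E14.5 to E16.5 for 4996 genes, 2167 upward and 2829 downward. Mme gained 6.72 ± 0.76, Leap2 6.50 ± 0.41, Meltf 6.26 ± 0.66, Mep1b 6.17 ± 0.77 and Hyal5 6.16 ± 0.57 (limma adjusted p from 3.29e-07 to 4.75e-05). Krt13, Atp4a, Gkn1, Krtdap and Gkn2 changed by -5.82 ± 0.43, -5.80 ± 0.34, -5.75 ± 0.66, -5.75 ± 0.61 and -4.89 ± 0.65. The Shh difference turned from 0.80 ± 0.22 to -2.74 ± 0.19, a change of -3.54 ± 0.29, and that of Sfrp5 fell by 2.38 ± 0.24. Early differences in Cdx2 (change -0.05 ± 0.36), Isx (0.04 ± 0.32) and Barx1 (-0.44 ± 0.35) were not called as changed. Smooth muscle genes went down for 16 of 19 and matrix genes for 18 of 21 (17 and 18 adjusted over the list alone), and transporters went up for 18 of 26 and down for 2 (19 and 2 adjusted over the list alone). The enteric neuron and glia list, down for 12 of 18 genes and up for 1 (14 and 1 adjusted over the list alone), kept its call (adjusted p = 0.0299 with an estimated correlation), unlike the other 16 called lists (adjusted p = 0.196 to 0.554 with an estimated correlation). Without duodenal replicate 3 of E14.5 the count was 3256.

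The pylorus minus stomach difference changed for 453 genes, 281 upward and 172 downward. Reg1, Smcp, the gluconeogenic enzyme Pck1, Clca4b and Leap2 gained 5.12 ± 1.04, 4.85 ± 0.41, 4.57 ± 0.38, 4.28 ± 0.60 and 4.19 ± 0.39 (limma adjusted p from 8.50e-06 to 0.0166). Krtdap, Krt13, Atp4a, Rptn and Krt4 changed by -5.50 ± 0.57, -5.07 ± 0.40, -4.95 ± 0.32, -4.50 ± 0.62 and -4.35 ± 0.28. The iron transporter Slc11a2 gained 2.85 ± 0.35 and Creb3l3 2.73 ± 0.50, and Nkx2-5 fell by 1.18 ± 0.25. Squamous genes went down for 7 of 12 (11 adjusted over the list alone), and that list kept its call (adjusted p = 0.0488 with an estimated correlation), while the other 15 called lists did not (adjusted p = 0.448 to 0.637 with an estimated correlation). The count was 274, 216 and 223 without E14.5 stomach replicates 1, 2 and 3, 701 and 248 without E14.5 pyloric replicates 1 and 2, 252 without E16.5 stomach replicate 3, and 299 and 209 without E16.5 pyloric replicates 1 and 2.

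The pylorus minus duodenum difference changed for 3561 genes, 2286 upward and 1275 downward. Sptssb, the sulfotransferase Sult1c2, Gkn1, Gkn2 and Plet1 gained 4.81 ± 0.73, 4.79 ± 0.47, 3.88 ± 0.66, 3.75 ± 0.65 and 3.53 ± 0.50, and Sox2 and Shh 3.34 ± 0.60 and 3.26 ± 0.29. Meltf, Naaladl1, Abcc2, Abcb11 and Bst1 changed by -4.27 ± 0.66, -3.91 ± 0.26, -3.89 ± 0.76, -3.67 ± 0.45 and -3.67 ± 0.63 (limma adjusted p from 3.71e-06 to 0.00311 over these 10 genes other than Sox2 and Shh). The nerve genes Stmn2, Hand2 and Elavl4 gained 2.29 ± 0.33, 1.77 ± 0.34 and 1.72 ± 0.27. Nkx2-5 and Gata3 changed by -1.22 ± 0.27 and -1.54 ± 0.52. The enteric neuron and glia list went up for 13 of 18 genes (15 adjusted over the list alone) and kept its call (adjusted p = 0.00960 with an estimated correlation), and 14 other called lists lost theirs (adjusted p = 0.433 to 0.698 with an estimated correlation). Among these lists 14 of 24 cell division genes and 12 of 28 Wnt genes gained (21 and 12 adjusted over the list alone). Without duodenal replicate 3 of E14.5 the count was 1673.

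**Figure D5:**
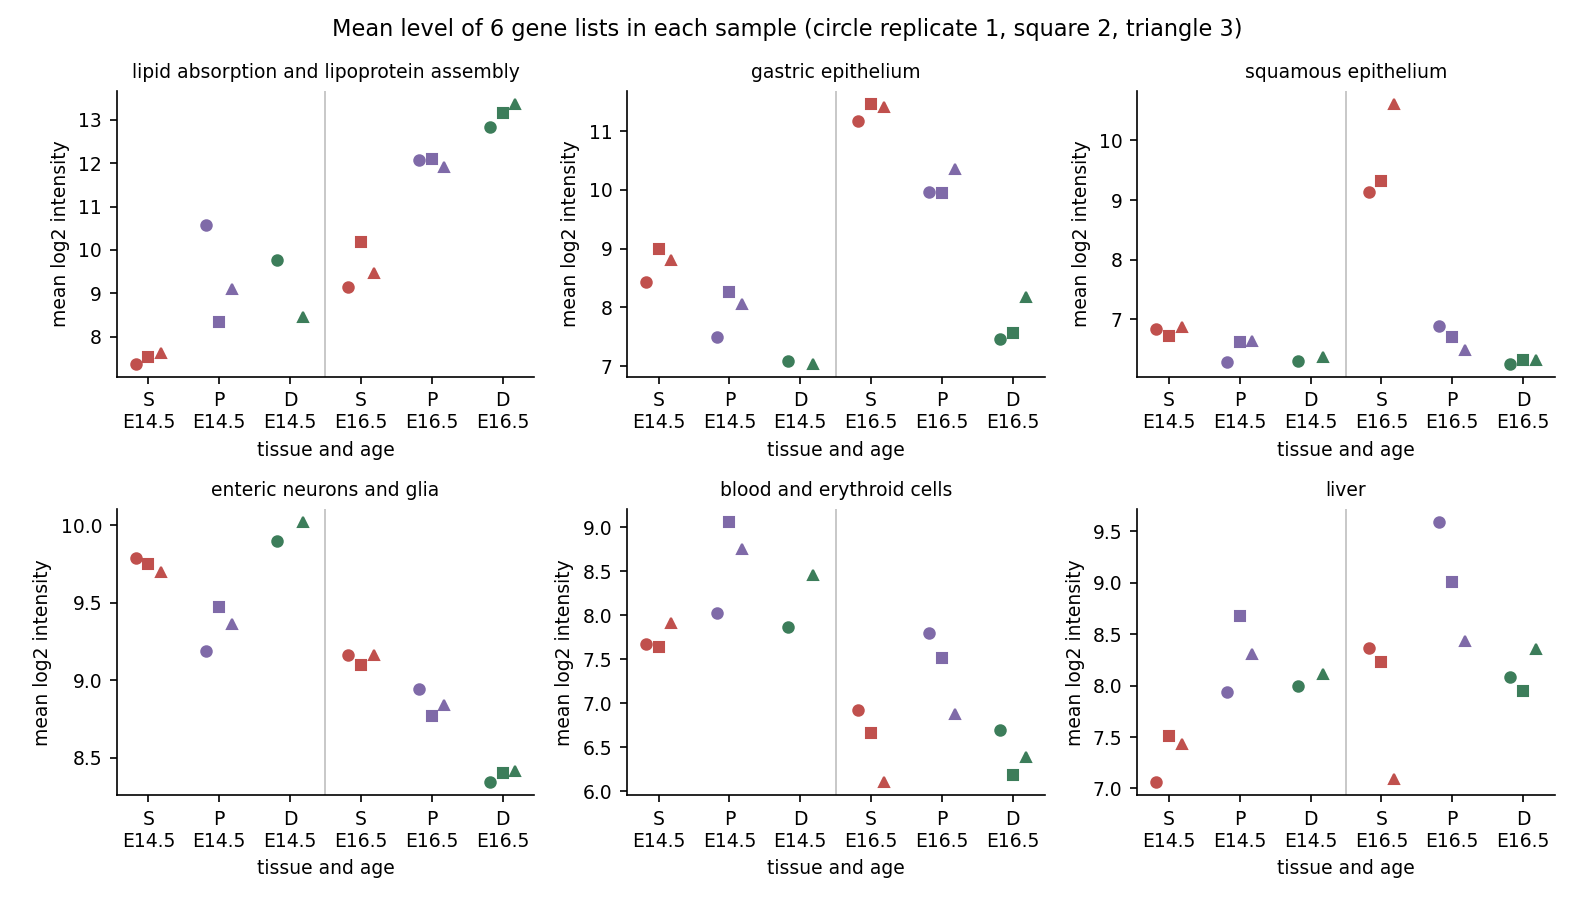
Mean log2 intensity of 6 gene lists (vertical axes) in each sample of stomach (S), pylorus (P) and duodenum (D) at E14.5 and E16.5 (circle, square and triangle for replicates 1, 2 and 3, with the averaged duodenal pair of E14.5 as a circle). The first E14.5 pylorus sample lies at 10.58 for the lipid list, above 8.34 and 9.11, and the liver and erythroid lists vary between pools of one group.

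Of the 190 list calls over all 12 comparisons, 7 held with an estimated correlation: the intestinal transcription factors in pylorus minus stomach at E14.5, the squamous genes in the change of that difference, and the enteric neuron and glia genes in 5 comparisons. Cholesterol synthesis genes were called as a list in none of the comparisons (with age they were called without stomach replicate 3 of E14.5, stomach replicate 1 of E16.5 or pyloric replicate 1 of E14.5), with medians from -0.11 to 0.39 and Dhcr7 higher in duodenum than in stomach at E16.5 by 1.46 ± 0.16. Pancreas genes were called as a list between duodenum and both other tissues at E14.5 alone. The endothelial list had a median of -0.71 with age in the pylorus, where 8 of 16 genes were lower, and the leukocyte list a median of 0.53 between pylorus and stomach at E14.5, where 4 of 15 were higher. Neither kept its call with an estimated correlation (adjusted p = 0.286 and 0.0588). Among lists that were not called, the median, the mean and the test differed in sign for several lists with small values, such as the Wnt list between duodenum and stomach at E14.5 (median -0.13, mean 0.12) and the pancreas list in the duodenum with age (median -0.12, mean 0.14).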

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

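The tests of the mixture and age explanations for the first E14.5 pylorus sample, of the link between liver and erythroid genes, and of a single squamous source were chosen only after the result was seen. The ranges given with the medians of these tests come from resampling genes. They show the spread between genes and hold no error between pools.

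The first E14.5 pylorus sample stood apart from the other pyloric samples of its age. For duodenum of the same age mixed into the pool, its intestinal genes were set against the higher duodenal value of each gene. They lay above it by a median of 0.27 (0.21 to 0.32, 582 genes). The duodenal samples themselves differed by a median of 0.40, so the test could not tell. Over genes that changed with age, the sample lay beyond the duodenal sample nearer to E16.5 by 0.22 of the step between ages (0.16 to 0.28, 189 genes), with a range of 0.11 over the other E14.5 samples. The genes and the axis were set from the stomach and duodenal samples, which holds these near 0 and narrows that range. Pyloric replicates 2 and 3, not used for this, lay at -0.00 and -0.01. The values argue against a mixture with duodenum like the measured samples, but not with duodenum that differs from them. E16.5 duodenum mixed into the pool was argued against, since genes that fall with age differed by -0.49 (-0.62 to -0.45, 105 genes) where the needed share of 6.9% allows -0.07. E16.5 pylorus was argued against by the same value, as its needed share of 24.6% allows -0.19. Both points hold only if pools otherwise differ by less over these genes, which was not tested. Older embryos in the pool could explain the genes that changed with age, as the sample lay at 0.29 on the age axis over 189 genes and no other E14.5 sample above 0.06. For its gastric genes older embryos were argued against, since the list stood lower than in the other pyloric samples, at a median difference of -0.53 (-0.96 to -0.17, 20 of 26 genes lower), while from those samples to E16.5 it rose by 1.65 (1.01 to 2.12). Between those samples, as replicate 2 minus replicate 3, the median difference of the gastric list was 0.15. Sox2 stood at 8.66 in replicate 1 against 10.77 and 10.65. Older embryos alone do not cover the whole pattern, nor does duodenum like the measured samples of the same age. Whether both together, other duodenum or another difference between pools set this sample apart stays open.

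Of 12 erythroid genes 4 were higher in the E16.5 pylorus than in the stomach and 6 than in the duodenum. Both list calls were lost with an estimated correlation (adjusted p = 0.462 and 0.547) and with fry (0.0714 and 0.0536), and the calls were lost without pyloric replicate 1 in both comparisons, without stomach replicate 3 in the first and without pyloric replicate 2 or duodenal replicate 2 in the other. Pyloric replicate 3 had a mean level of 6.88, below 6.92 in stomach replicate 1. Liver tissue or its blood in the pools may account for the erythroid genes, since the erythroid and liver lists went together within groups (r = 0.81, permutation p = 0.00213, rho = 0.78, p = 0.00341, 17 samples, 1 relation tested, and r = 0.77 without the 2 farthest). No other list was set against the erythroid list, so the link need not be particular to liver. With the liver level as a covariate Hbb-y went from 2.26 ± 0.69 to 0.39 ± 0.65 and Slc4a1 from 2.04 ± 0.57 to 0.28 ± 0.43, while Nepn went from 4.09 ± 0.35 to 3.31 ± 0.39 (adjusted p = 1.36e-04) and Gata3 from 1.35 ± 0.35 to 1.16 ± 0.48 (adjusted p = 0.181). The falls of Hbb-y and Slc4a1 follow from the correlation of the lists and are no separate evidence. For the other 261 genes higher in pylorus than in both, the median of the smaller difference was 0.40 with the covariate, against 0.49 before. It kept the share predicted if liver was not their source, yet the count fell from 266 to 32. Only 5 of the 266 genes are in the liver and erythroid lists, so the 261 may still hold other genes of liver or blood. A median over all of them therefore cannot tell. Over the 261 genes the median difference from stomach went from 0.58 to 0.46 and its median error from 0.15 to 0.19, and those from duodenum from 0.60 to 0.53 and from 0.15 to 0.18. The error was larger with the covariate for 256 and 251 of them, but smaller from stomach for Hbb-y and Slc4a1, which are in the erythroid list. The liver list holds Cps1, a gene of liver and gut, so the covariate does not measure liver alone. How many of the 266 genes are free of liver admixture stays open.

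Squamous genes were high in the stomach at E16.5 and not in other groups. Whether one squamous source in different amounts gave them was not decided. From replicate 2 to replicate 3 the cornified envelope genes moved by -2.50 (-3.76 to -1.57, 6 genes) and the squamous list by 1.12 (0.40 to 2.64, 12 genes). The cornified envelope genes were picked for their high level in replicate 2, so this comparison decides nothing and a single source stays open. Forestomach-like epithelium of different maturity in the pools was not tested and stays open.

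The 3 tissue differences were marked because they changed between ages, for 4996 genes in duodenum minus stomach, 453 in pylorus minus stomach and 3561 in pylorus minus duodenum. Genes called in opposite directions at the ages numbered 95 in duodenum minus stomach. In pylorus minus stomach they numbered 2, Afm (-0.71 to 0.62, change 1.34, adjusted p = 0.0105) and Hopx (1.41 to -1.17, change -2.58, adjusted p = 0.00728). In pylorus minus duodenum they numbered 23, such as Hhex (-0.70 to 1.10) and Nefm (-1.13 to 1.07). Shh turned by -3.54 in duodenum minus stomach and by 3.26 in pylorus minus duodenum. List medians that turned were smooth muscle by -1.11 in duodenum minus stomach and -0.46 in pylorus minus stomach, endothelium by -0.62 in pylorus minus stomach, and in pylorus minus duodenum lipid absorption by -1.36, the Wnt list by 0.52 and enteric neurons and glia by 1.05. Without single samples 4 of these turns lost a call on one side, and 1 of them its sign. Without stomach replicate 3 of E16.5 the pylorus minus stomach medians at that age went from -0.30 to -0.06 for smooth muscle and from -0.39 to -0.25 for endothelium, and neither list was called. At E14.5 neither was called without pyloric replicate 1 (0.14 and 0.05). Smooth muscle was not called at E16.5 without pyloric replicate 3 (-0.20), nor endothelium at E14.5 without stomach replicate 2 or 3 (0.09 and 0.14). The lipid difference between pylorus and duodenum at E14.5 went from 0.13 to -0.29 without pyloric replicate 1 and to -0.19 without duodenal replicate 3, so it did not turn there. The Wnt list was not called at E14.5 without pyloric replicate 1 or 2 or duodenal sample 1. All 6 changes were called without each sample in turn, at -0.25 for smooth muscle and -0.42 for endothelium in pylorus minus stomach without stomach replicate 3, and at -0.80 for lipid absorption without pyloric replicate 1. Few or no members were called on one side of some turns. In pylorus minus stomach limma called 0 of 19 smooth muscle and 0 of 16 endothelial genes at E14.5 (4 and 0 at unadjusted p under 0.05), 1 and 3 at E16.5, and 0 of either as changed (7 and 5 at unadjusted p under 0.05). In pylorus minus duodenum it called 0 of 20 lipid genes at E14.5 (0 at unadjusted p under 0.05) and 12 at E16.5. With an estimated correlation the change kept its call for enteric neurons and glia alone (adjusted p = 0.00960, and 0.305 to 0.499 for the other 5). At E14.5 the estimated-correlation p of endothelium was 0.7 and that of lipid absorption 0.734.

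Other splits of the samples were compared with the real grouping. For pylorus minus stomach at E14.5 (649 genes, highest other split 0), duodenum minus stomach (8387, highest other 1), pylorus minus stomach (3894, highest other 3) and pylorus minus duodenum (6731, highest other 9) at E16.5, and for the change with age in stomach (7433, highest other 0) and pylorus (7312, highest other 9), only 1 of 10 splits reached the real count, too few to tell. For the change of pylorus minus stomach with age, 7 of 100 splits reached 453 genes and the highest other called 2106, so chance was not excluded. In each of the other splits that reached it, the E16.5 samples stayed together by tissue while those of E14.5 were mixed, so these counts, some several times the real one, point to a structure of the samples, the tissue difference at E16.5. For genes higher in pylorus than in both neighbours at E16.5, 3 of 100 splits, the real one among them, reached 266, fewer than was predicted for chance. Most splits mixed tissues that differ widely at E16.5, which widens the spread within groups and lowers their counts. The result therefore does not tell whether the 266 genes arose by chance. The highest other called 2372, with the 3 duodenal samples in the place of the pylorus, and a further split called 1268 with the 3 stomach samples there, so both follow the tissues.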

How the results depend on the processing

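With all named probe sets tested, genes higher in pylorus than in both neighbours numbered 8 at E14.5 and 433 at E16.5, and after quantile normalization 6 and 162. With only genes above the median of the gene means, and so fewer genes, the counts were 759, 421 and 54 for duodenum minus stomach, pylorus minus stomach and pylorus minus duodenum at E14.5, 5504 and 4470 for duodenum minus stomach and pylorus minus duodenum at E16.5, 4838, 4630 and 6464 for stomach, pylorus and duodenum with age, 218 for the change of pylorus minus stomach, and 1 for higher than both at E14.5. With only the groups compared, the counts at E14.5 were 2638, 375 and 0 by limma (1327 at unadjusted p under 0.05) in the same order and 5 for higher than both. With the replicate number as a block, higher than both at E14.5 was 6. Of 35 same-numbered pairs of samples 13 correlated above 0.1 (r from -0.258 to 0.43), and pairs with different numbers were not compared. Between the E16.5 tissues the pairs of replicate 2 correlated at 0.353, 0.430 and 0.346, and those of replicates 1 and 3 at -0.132 to 0.166. Whether the numbers pair samples stays open. All 18 arrays as separate samples, an alternative chosen after seeing the data, gave 1949 for duodenum minus stomach, 310 for pylorus minus duodenum and 9 for higher than both at E14.5. With the 3 doubted arrays left out, also chosen after seeing the data, these were 2266, 742 and 107, with 443 for higher than both at E16.5 and 890 for the change of pylorus minus stomach. Differences near 0 changed sign. For Cdx2, pylorus minus duodenum at E14.5 was -0.383 to 0.077 and at E16.5 -0.122 to 0.038 without 1 sample (0.027 at E16.5 with the mean of probe sets). The change of duodenum minus stomach was -0.280 to 0.288 for Cdx2 (0.076 with the mean of probe sets, 0.027 with all 18 arrays) and -0.190 to 0.255 for Isx (-0.205 without the doubted arrays). Vil1 in pylorus minus duodenum at E14.5 was -0.662 to 0.088, and Six2 in pylorus minus stomach reached -0.027 without pyloric replicate 2. With a 2-fold threshold the position at E16.5 was 0.408. Leaving out 1 sample gave 430 to 784 for duodenum minus stomach, 351 to 791 for pylorus minus stomach and 14 to 420 for pylorus minus duodenum at E14.5, 2482 to 3981 for pylorus minus stomach at E16.5, 3256 to 5680, 209 to 701 and 1673 to 4386 for the changes of duodenum minus stomach, pylorus minus stomach and pylorus minus duodenum, and 2 to 52 and 132 to 295 for higher than both at E14.5 and E16.5. What caused these shifts was not tested. Where 1 duodenal sample of E14.5 remained, it was assumed to vary like the other groups. The mean of probe sets, median centring and a trend with a robust prior moved no count by more than 1.5 times. Of the 190 list calls, fry kept 139, quantile normalization 183, the mean of probe sets 177, genes above the median 139, the replicate block 181 and an estimated correlation 7. With each sample left out in turn, chosen after seeing the data, 141 of them held without every sample and 49 were lost or turned without at least 1. Those that turned lay in pylorus minus duodenum at E14.5, where the median was -0.294 to 0.747 for lipid absorption, -0.333 to 0.310 for goblet and Paneth cells and -0.507 to -0.160 for enteroendocrine cells, whose test turned up. The linear-scale alternative was not run, since the values are log2.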

Other observations

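Interferon-stimulated genes, which answer viral and nucleic acid signals, were high in the duodenum at E16.5. These lists and genes were chosen after their values were seen. The mean level of 6 such genes was 7.70, 8.71 and 9.75 in the 3 duodenal pools and no higher than 6.89 in any other sample. Against the stomach, Ifit1 was higher by 5.47 ± 0.33, Irf7 by 2.76 ± 0.27 and Rsad2 by 2.62 ± 0.38 (n = 3 per group), and all 6 genes were called, with a median of 2.59. Against the pylorus all 6 differed as well, with Ifit1 at -2.63 ± 0.33 in pylorus minus duodenum. With age in the duodenum Ifit1 rose by 4.43 ± 0.37. At E16.5 Ifit1 was also higher in pylorus than in stomach, by 2.84 ± 0.33, the 1 gene of the 6 called there. With age in the pylorus 2 of the 6 were called, Ifit1 at 1.78 ± 0.33 and Irf7 at 1.04 ± 0.27. As a list the 6 genes were called between duodenum and stomach by camera (adjusted p = 0.00115) and not with an estimated correlation (adjusted p = 0.459).

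Imprinted growth genes, 7 in the list, were called as a list with age in stomach (6 lower, adjusted p = 0.00480) and pylorus (4 lower, 0.00479) and not in duodenum (4 lower and 2 higher, 0.0596). Of these genes Mest, Dlk1 and Peg3 fell in the duodenum by 2.27 ± 0.15, 2.29 ± 0.22 and 2.28 ± 0.18, while Cdkn1c and Igf2 rose by 0.48 ± 0.12 and 0.25 ± 0.09. In the pylorus Mest, Dlk1 and Peg3 fell by 1.15 ± 0.14, 0.76 ± 0.20 and 1.19 ± 0.16. In the stomach Mest and Peg3 fell by 0.97 ± 0.14 and 0.86 ± 0.16, and Dlk1 was not called (0.03 ± 0.20). The change of duodenum minus stomach was called for all 3 genes, at -1.29 ± 0.20, -2.32 ± 0.29 and -1.42 ± 0.24 for Mest, Dlk1 and Peg3. In the duodenum 19 of 21 matrix genes, 15 of 18 enteric neuron and glia genes and all 24 cell division genes fell with age as well, and whether the 3 genes fell apart from these was not tested. By camera the list was also called lower in pylorus minus stomach, at E14.5 (no member called, adjusted p = 0.00379) and at E16.5 (2 lower, 0.0120). These genes too were chosen after their values were seen, and the list did not pass with an estimated correlation in any comparison.

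Immediate-early and heat-shock genes, also chosen after their values were seen, had a median change with age of 1.76 in stomach and 1.46 in duodenum, with 7 of 16 genes called in each. The list was called in stomach (adjusted p = 0.00480, and 0.503 with an estimated correlation) and not in duodenum (0.0596 and 0.747). At E16.5 camera also called it lower in pylorus minus stomach (adjusted p = 0.00247) and pylorus minus duodenum (0.0208). The changes of both differences with age were called too (1.35e-04 and 0.0126). With an estimated correlation these calls were lost (0.400 to 0.749). Single pools weighed most, with mean levels of 11.33 in stomach replicate 3 and 11.28 in duodenal replicate 1. The other E16.5 pools were at 9.12 and 8.75 in stomach and at 9.05 and 9.22 in duodenum, and the E14.5 samples at 8.16 to 8.36 and at 8.37 and 8.51.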
